A study of Mus musculus with 6 samples.

How the data were processed

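RNA from CD4+CD25+ regulatory T cells of Balb/c mice was measured on 6 single-colour arrays, 3 from wild-type and 3 from Mbd2 knockout mice. Per the labels' protocols, total RNA was isolated on columns, amplified and labelled with biotin. The deposited values are log2 expression values per probe set. Per the submitters' processing notes the authors used RMA, a method that corrects background, normalizes by quantiles and summarises the probes of a probe set. Its software, its version and which arrays were normalized together are not given in the sources used here. Quantile normalization of all arrays together would give them near-equal distributions, and wild-type replicate 3 had another SD and other quartiles than the rest. No correction for this was made in the values as reported, and array totals give no depth. The number of arrays limits the precision.

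Groups were taken from the sample titles and genotype labels. Of 22690 probe sets, 64 were control probe sets and were left out. Gene symbols came from the platform's annotation table, updated by gene ID through the RefSeq table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only. Among 22626 other probe sets, 20380 had 1 gene symbol, 691 had several and 1555 were not listed, and no gene was named from the last 2 kinds. Of the single symbols 20351 were found by gene ID and 29 were kept as given.

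The 40% of probe sets with the lowest mean over the 6 arrays were left out (mean log2 under 5.18). The remaining 13575 were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each of 8190 genes was represented by its probe set with the highest mean, and adjusted p-values of genes are those over all tested probe sets. Of 126 list genes with several tested probe sets, 30 had a probe set of opposite sign with 6 arrays and 22 without wild-type replicate 3. The Mbd2 probe sets were tested without the filter. The values came without detection calls. A fold whose lower group mean lay under the filter cutoff was therefore given as a lower bound, with the arrays of that group raised to the cutoff, a rule added after the data were seen; log2 differences are as measured.

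Genes to be named were those past the threshold without overlap between groups, up to 12 per direction by size. With fewer than 20 genes called, all were named and each direction was filled to 10 genes by smallest p, said to be ranked and not called. Mbd2 and Foxp3 were always named, with up to 4 members of each list by smallest p and any list member past the threshold. The repeat without wild-type replicate 3 used the same rule.

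There were 28 gene lists, written from general knowledge before the data were examined, with 523 of 526 symbols matched. One of them held the 30 protein-coding genes on each side of Mbd2. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists tested. Camera with an estimated correlation and fry were run beside it. The lists of germline and sex-linked genes had 0 and 2 measured genes and were not tested.

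The following alternatives were chosen before the data were examined: no filter, a filter on the lowest 60%, a trended robust variance model, array quality weights, a further quantile normalization, median centring, the replicate number as a block, each array left out in turn, an adjusted p under 0.1, an unadjusted p under 0.05 with at least a 1.5-fold difference, and the mean of a gene's probe sets. Leaving out wild-type replicate 3 and knockout replicate 2 together was added after the data were seen, and so was the decision to lead with the fit without wild-type replicate 3 beside that of 6 arrays.

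The fit was tested on simulated data with 200 changed probe sets, 50 at each fold. With 6 arrays it recovered 4% of 2-fold, 54% of 4-fold, 92% of 8-fold and 94% of 16-fold changes, with 4 false calls. Without wild-type replicate 3 it recovered 90% of 2-fold changes and 100% of the larger ones, with 17 false calls. Each fit used a single draw, with independent noise of the same spread on every array. In the data wild-type replicate 3 stood apart, so the figures for 6 arrays describe a setting unlike the data. In 20 further draws with the spread of the fit without wild-type replicate 3, added after the data were seen, 2-fold changes were recovered at a mean of 93.3% with 6 arrays, 89% with 5 and 82.3% with 4. Figures were drawn with matplotlib 3.10.9.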

Results

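Gene expression was measured in CD4+CD25+ regulatory T cells (Treg), the subset of helper T cells that restrains immune responses, after magnetic separation from Balb/c mice. There were 2 groups of 3 arrays each: cells from wild-type mice and cells from mice lacking Mbd2, a protein that binds methylated DNA. The study's title names the demethylation of Foxp3, which encodes the lineage-defining transcription factor of Treg, and Treg function. The arrays compared RNA levels only. The submitters described the samples as independent, so the limma p-values of single genes measure the spread between such samples. Camera p-values at the preset correlation set the genes of a list against the other genes and do not measure that spread. With arrays of both groups mixed, camera called up to 13 lists, against 10 for the real groups.

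The deposited log2 values covered 22690 probe sets on each array, with array medians from 5.56 to 5.78. Wild-type replicate 3 stood apart from the other 5 arrays. Its Pearson correlation with them, across probe sets, lay between 0.749 and 0.767, while all pairs without it lay between 0.956 and 0.997. Its SD across probe sets was 1.37, and its quartiles were 5.0 and 6.64, against 4.58 and 7.30 in wild-type replicate 1. The next lowest correlations belonged to Mbd2 knockout replicate 2, and without both arrays the lowest was 0.983. Values are therefore given with all 6 arrays, as fixed before the data were examined, and for the other 5 arrays without wild-type replicate 3 (the 5-array fit), a fit given this place after its correlations were seen.

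**Figure D1:**
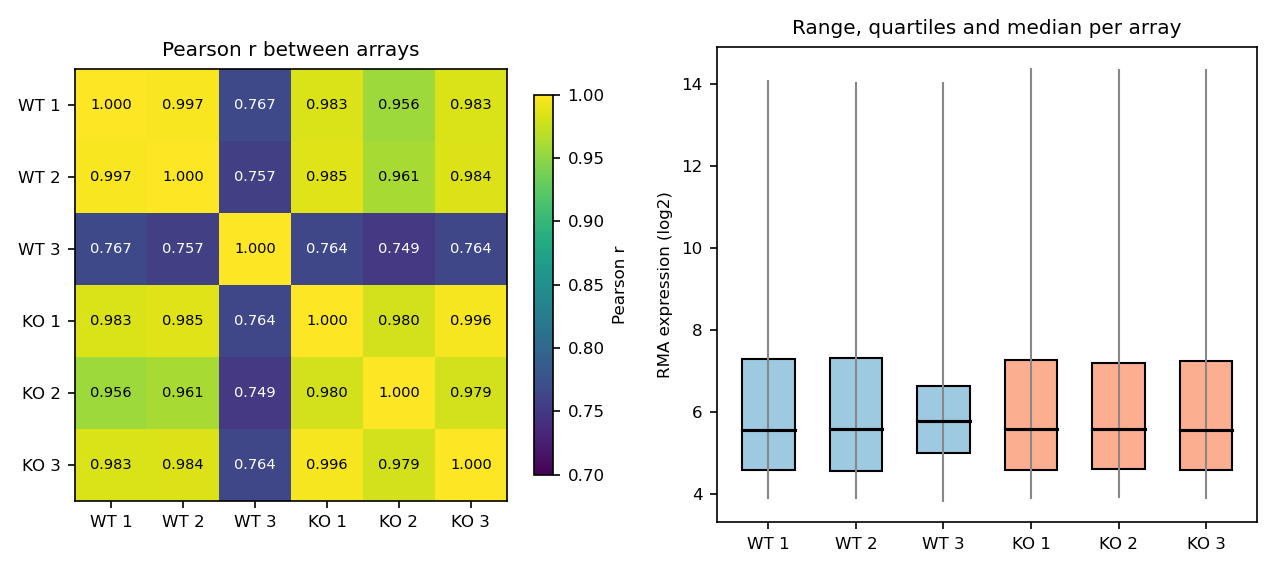
The left panel gives the Pearson r across probe sets for each pair of arrays (WT, wild type; KO, Mbd2 knockout), and the right panel the range (line), quartiles (box) and median (bar) of log2 expression on each array. Wild-type replicate 3 correlated with the other arrays at 0.749 to 0.767 and had a narrower box than the other 5.

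The first comparison asked whether the targeted transcript was lower in the knockout cells. Both Mbd2 probe sets were lower in all 3 knockout arrays than in all 3 wild-type arrays. The brighter probe set gave 8.13 ± 1.04 (SD, n = 3) in wild type and 5.92 ± 0.21 (SD, n = 3) in knockout, a log2 difference of -2.21. The dimmer probe set gave 6.67 ± 0.28 (SD, n = 3) and 4.63 ± 0.06 (SD, n = 3), a log2 difference of -2.04. In the limma fit of 6 arrays without a filter on dim probe sets, neither passed the threshold, with adjusted p of 0.817 and 0.0744. In the 5-array fit, both passed, at -2.80 (adjusted p = 0.00348) and -2.18 (adjusted p = 0.00238). Mbd2 in wild-type replicate 3 was 6.93 and 6.38 on these probe sets, above every knockout array. Whether the probe sets lie in the deleted part of the gene is not given in the sources used here, and a probe set outside it would not check the labels.

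The level of Foxp3, measured by 1 probe set, was 8.83, 8.74 and 6.93 in wild-type replicates 1, 2 and 3, and 7.98, 6.62 and 8.17 in knockout replicates 1, 2 and 3. The log2 difference was -0.58 with an SE of 0.65, and the groups overlapped (limma adjusted p = 0.829). With 5 arrays, it was -1.19 with an SE of 0.46, which did not pass the threshold either (limma adjusted p = 0.21). It passed with array quality weights, at -0.76 (adjusted p = 0.0344), and without both wild-type replicate 3 and knockout replicate 2, at -0.71 (adjusted p = 0.00482). Without knockout replicate 2 alone it was -0.09 (adjusted p = 0.97), and it was -0.25 and -0.29 without wild-type replicates 1 and 2.

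**Figure D2:**
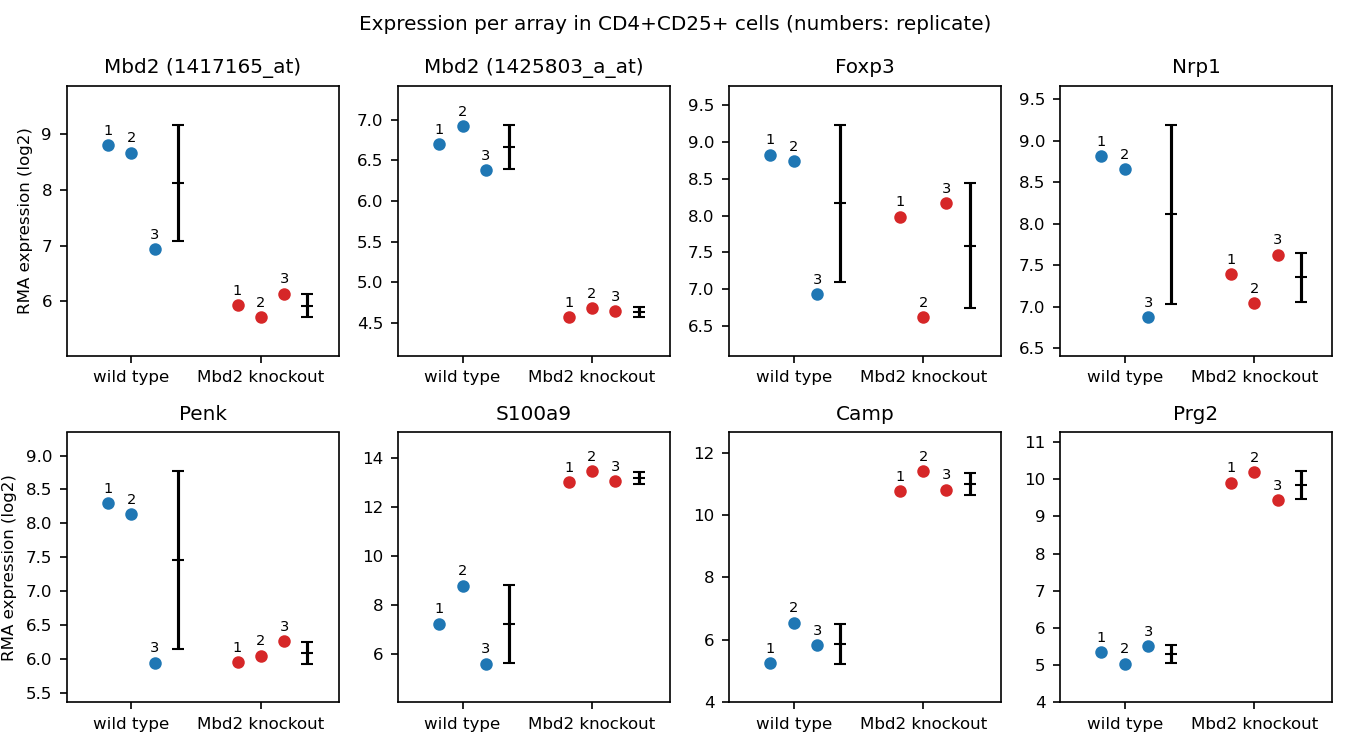
Log2 expression of Mbd2 (the brighter probe set, then the dimmer), Foxp3, Nrp1, Penk, S100a9, Camp and Prg2 on each array (points, numbered by replicate; blue, wild type; red, Mbd2 knockout), with the mean and SD of the 3 arrays of each group (bars); each panel has its own axis, which does not start at 0. Camp and Prg2 lay far higher in all 3 knockout arrays, and Foxp3 overlapped between the groups.

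The main comparison set knockout against wild-type cells over 13575 probe sets. Sex was not a term in the fit, although the Y-linked gene Eif2s3y was high in knockout replicates 2 and 3 only. With 6 arrays, 14 probe sets passed the threshold, 14 of them higher and 0 lower in knockout. They held 10 of the 8190 genes tested, and 3 of the probe sets, which rose 44.3-fold, 39.9-fold and at least 18.6-fold, had no gene in the annotation table. The 10 named genes were mostly genes of granulocytes and other myeloid cells. Camp, the cathelicidin antimicrobial peptide of neutrophil granules, rose 34.9-fold (log2 difference 5.12, SE 0.39, adjusted p = 0.0133). Ngp, another neutrophil granule protein, rose 33.6-fold from 7.08 ± 0.85 to 12.15 ± 0.36 (SD, n = 3 each). Ltf and Lcn2, which encode the iron-sequestering proteins lactoferrin and lipocalin 2, rose by log2 differences of 4.92 and 4.91. The lysozyme genes Lyz2 and Lyz1 rose 25.4-fold and 22.1-fold. Prg2, the major basic protein of eosinophils, rose 23.5-fold (SE of the log2 difference 0.28, adjusted p = 0.0054). Chil3, a chitinase-like protein of myeloid cells, rose at least 13.03-fold, Wfdc21 at least 9.40-fold and F13a1, a subunit of coagulation factor XIII found in monocytes and platelets, at least 9.49-fold. These are lower bounds, since the wild-type means of these 3 genes (4.66, 4.92 and 4.94) lay under the filter cutoff of 5.18. All 10 genes stayed past the threshold without wild-type replicate 3. No gene was called without knockout replicate 1 or without knockout replicate 2, and 1 gene was called without knockout replicate 3. The sizes were kept in these 3 fits, where the log2 differences of the 10 genes lay between 3.19 and 5.24, against 3.49 to 5.12 with 6 arrays.

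No gene was called lower with 6 arrays. The limma fit gave 554 probe sets at an unadjusted p under 0.05, of which 473 were higher and 81 lower. As a share of the 13575 tested, this is less than the 0.05 that would fall there with no difference. Without wild-type replicate 3 the tilt turned, with 943 higher and 1987 lower. The 10 lower genes with the smallest p, which are ranked and not called, were Nckap1, Ccl1, Mbd2, Prrt1, Slc7a10, Slc22a2, Sytl1, Arhgef5, Sapcd1 and Arl2bp. Their log2 differences ran from -0.76 for Arhgef5 to -2.21 for Mbd2, and the chemokine gene Ccl1 was at -1.11 (adjusted p = 0.433). The median log2 difference over all tested probe sets was 0.15 with 6 arrays and -0.06 without wild-type replicate 3. Only 53.7% of genes kept their direction between these fits.

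Without wild-type replicate 3, 190 probe sets passed the threshold, 91 higher and 99 lower, and 129 genes, 67 higher and 62 lower. Among probe sets with a gene symbol, the largest rises were again those of granulocyte and myeloid genes, while the 3 probe sets without one rose 39.1-fold, 38.7-fold and at least 18.8-fold. S100a9 and S100a8, which encode the subunits of calprotectin, rose 35.8-fold and 30.5-fold. Hp, which encodes haptoglobin, rose at least 9.59-fold and Ifitm6 at least 16.5-fold, from wild-type means of 4.90 each. The 12 largest rises of named genes also held Ngp, Camp, Ltf, Lyz2, Lcn2, Lyz1, Prg2 and Chil3, all 10 genes of the 6-array fit except Wfdc21 and F13a1.

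The largest falls without wild-type replicate 3 included several genes of Treg and of T cell migration. After Mbd2, the largest fall was that of Penk, which encodes proenkephalin and is expressed in Treg (log2 difference -2.13, SE 0.13, adjusted p = 0.00299). Cxcr3 and Ccr6, chemokine receptors of effector T cells, fell 3.82-fold and 2.48-fold. Tnfsf11, which encodes the cytokine RANKL, fell 3.09-fold. Nrp1, a surface marker of thymus-derived Treg, fell 2.61-fold (log2 difference -1.39, SE 0.18, adjusted p = 0.0349). Ptger2, a prostaglandin E receptor, fell 2.51-fold and Gimap7, a lymphocyte GTPase, 2.32-fold. Sapcd1, Capn3, Slc7a10 and Ccl1 completed the 12 largest falls. None of these falls passed the threshold with 6 arrays, where Penk was at -1.37 (adjusted p = 0.829) and Nrp1 at -0.76 (adjusted p = 0.829). In wild-type replicate 3 both Penk and Nrp1 lay below their knockout means.

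Gene lists fixed before the data were examined described the groups of genes. With 6 arrays, camera with a preset correlation of 0.01 called 10 of 26 tested lists, 9 higher and 1 lower in knockout. None of the 10 passed with an estimated correlation, and fry called 1. In the 5-array fit, the count was 13 lists, 9 higher and 4 lower, of which 9 were among the 10. Again 0 passed with an estimated correlation, and fry called 3.

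Neutrophil and granulocyte markers were the list with the largest shift. Of its 17 measured genes, 17 were higher in knockout and 6 passed the threshold over all genes, 14 when adjusted over the list alone. The median log2 difference was 2.74 (camera adjusted p = 2.4e-33), with adjusted p = 0.0809 with an estimated correlation and 0.004 by fry. The mast cell and basophil genes Mcpt8 and Cpa3 belonged to this list, at 2.61 and 1.86, neither past the threshold over all genes. With 5 arrays, 12 of the 17 genes passed and the median was 2.95 (camera adjusted p = 2.68e-21, adjusted p = 0.35 with an estimated correlation, 0.0149 by fry).

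Marker lists of several other cell types moved in the same direction. All 18 myeloid and dendritic cell markers were higher in knockout, with a median of 1.53 (camera adjusted p = 6.05e-19; adjusted p = 0.278 with an estimated correlation). Of these, 2 passed over all genes, Lyz2 and Lyz1, and 10 when adjusted over the list alone. The macrophage receptor gene Csf1r was at 3.07 (adjusted p = 0.14) and Mpeg1 at 2.61 (adjusted p = 0.208). All 14 B cell markers were higher, with a median of 1.74 (camera adjusted p = 2.02e-14; adjusted p = 0.227 with an estimated correlation). None passed over all genes and 11 did when adjusted over the list alone. Spib was at 1.62 and the antigen presentation genes H2-Ab1 and Cd74 at 2.27 and 2.21. All 7 plasma cell markers were higher, with a median of 1.5 (camera adjusted p = 0.00066; adjusted p = 0.585 with an estimated correlation), and 0 passed singly. The median was 1.11 without wild-type replicate 3 (camera adjusted p = 0.000772; adjusted p = 0.436 with an estimated correlation), 0.74 without knockout replicate 2 (camera adjusted p = 0.019) and 0.72 without both arrays (camera adjusted p = 0.000696; adjusted p = 0.399 with an estimated correlation). Jchain, the joining chain of polymeric antibodies, was at 1.87 and Xbp1 at 1.69.

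Of 14 CD8 T cell and NK cell markers, 13 were higher, with a median of 1.21 (camera adjusted p = 1.3e-06; adjusted p = 0.585 with an estimated correlation). The median was 0.57 without wild-type replicate 3 (camera adjusted p = 6.14e-06; adjusted p = 0.406 with an estimated correlation), 0.77 without knockout replicate 2 (camera adjusted p = 0.000677) and 0.26 without both arrays (camera adjusted p = 0.00112; adjusted p = 0.399 with an estimated correlation). None passed over all genes, and 3 did when adjusted over the list alone: Tyrobp at 2.78 and Fcer1g at 2.56, adaptor genes also used by myeloid cells, and the transcription factor gene Eomes at 1.38. These 3 genes passed in the 5-array fit over all genes, as did Spib among the B cell markers. Erythroid and platelet markers had a median of -0.13 with 6 arrays (camera adjusted p = 0.726). With 5 arrays, the list rose, with a median of 0.22 over 6 genes (camera adjusted p = 0.00762; adjusted p = 0.382 with an estimated correlation). The stromal list, of 4 genes, was not called (camera adjusted p = 0.94), although Vcam1 was at 2.97 (adjusted p = 0.433), and its median of -0.13 and its test differed in sign. Thymocyte markers were not called (camera adjusted p = 0.726).

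The Treg core signature had a median of -0.26 with 6 arrays, with 18 of 29 genes lower and 11 higher, and was not called (camera adjusted p = 0.0537). Lag3 and Gzmb, which encode an inhibitory receptor and granzyme B, were higher at 0.75 and 1.32, and Ikzf4, which encodes the Treg transcription factor Eos, was lower at -1.06. None of these 3 passed the threshold. In the 5-array fit, the list fell, with a median of -0.54 (camera adjusted p = 0.00144; adjusted p = 0.35 with an estimated correlation; 0.0122 by fry). Then 21 of 29 genes were lower and 5 passed over all genes, namely Penk, Nrp1, Icos, Cd83 and Itgae. When adjusted over the list alone 11 fell and 2 rose. The call depended on the setting also where wild-type replicate 3 was kept. The list was called lower with the filter on the lowest 60% (camera adjusted p = 0.000762). It was also called lower after quantile normalization again (median -0.35, camera adjusted p = 0.00507). The same held without knockout replicate 1 (camera adjusted p = 0.0467) and without knockout replicate 3 (camera adjusted p = 0.0362). Array quality weights nearly left out wild-type replicate 3, with a weight of 0.0289 against 0.448 to 8.24 for the other arrays. Wild-type replicate 1 had 0.448 against 4.39 for wild-type replicate 2, so the wild-type side rested mostly on replicate 2. Knockout replicate 2 had 0.585, and the weight estimation stopped before converging. With these weights the list was called lower too (camera adjusted p = 2.21e-05). It was not called without the filter (camera adjusted p = 0.279) or without knockout replicate 2 (median -0.10, camera adjusted p = 0.0995), and its median turned to 0.05 without wild-type replicate 1 (camera adjusted p = 0.307) and to 0.13 without wild-type replicate 2 (camera adjusted p = 0.395). All these tests used the preset correlation, and with an estimated one the 6-array fit gave an adjusted p = 0.866. The myeloid, granulocyte and B cell lists were higher in the same arrays, with medians of 1.6, 2.95 and 1.46.

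Effector and activated Treg genes had a median of -0.26 and a mean of 0.03 with 6 arrays and were not called (camera adjusted p = 0.0959). With 5 arrays, the list fell, with a median of -0.54 (camera adjusted p = 0.0138; adjusted p = 0.406 with an estimated correlation). In that fit 6 of 19 genes passed, all lower: Cxcr3, Ccr6, Batf, Rora, Tnfrsf1b and Icos. The lists share genes, so their falls are not separate results. Icos is also in the Treg core signature. Cxcr3 and Ccr6 are also among the chemokine receptors and homing genes, as is Itgae of the Treg core signature. Where wild-type replicate 3 was kept, the list was called lower with the filter on the lowest 60% (camera adjusted p = 0.00104). The same held after quantile normalization again (median -0.47, camera adjusted p = 0.00384) and without knockout replicate 2 (camera adjusted p = 0.0167). The list was also called lower with array quality weights, which nearly left that array out (camera adjusted p = 2.21e-05). Without wild-type replicates 1 and 2 in turn, its median was 0.05 (camera adjusted p = 0.314) and 0.11 (camera adjusted p = 0.486). Chemokine receptors and homing genes fell with 6 arrays (camera adjusted p = 0.008; adjusted p = 0.866 with an estimated correlation), with a median of -0.10 and 9 of 14 genes lower. That call was lost and the median turned to 0.04 without wild-type replicate 1 (camera adjusted p = 0.114) and to 0.11 without wild-type replicate 2 (camera adjusted p = 0.191). In the 5-array fit, the median was -0.59 (camera adjusted p = 4.06e-05; adjusted p = 0.35 with an estimated correlation; 0.0122 by fry), and Cxcr3, Ccr6, Itgae and Ccr9 fell. Genes of T cell receptor signalling had a median of -0.10 (camera adjusted p = 0.0537). With 5 arrays, they fell as a list, with a median of -0.39 and 17 of 18 genes lower (camera adjusted p = 0.0065; adjusted p = 0.624 with an estimated correlation), and no gene passed singly. Cd3g was then at -0.79 and Cd3e at -0.60. Where wild-type replicate 3 was kept, this list was called lower with the filter on the lowest 60% (camera adjusted p = 0.00622). It was also called lower after quantile normalization again (median -0.42, camera adjusted p = 2.64e-05) and with the mean of probe sets (camera adjusted p = 0.021). The same held without knockout replicate 1 (camera adjusted p = 0.0138) and without knockout replicate 3 (camera adjusted p = 0.0101). Array quality weights, which nearly left out wild-type replicate 3, gave a call too (camera adjusted p = 0.00849). The median of the list turned to 0.03 without wild-type replicate 1 and to 0.01 without wild-type replicate 2. It turned to 0.12 without knockout replicate 2, and none of these 3 was called. Without both wild-type replicate 3 and knockout replicate 2 the median was -0.17, a smaller fall than the -0.39 with 5 arrays. The list was then called lower (camera adjusted p = 0.00208, adjusted p = 0.397 with an estimated correlation, 0.032 by fry).

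Lists of proliferation and protein folding genes were higher in the same knockout arrays as the granulocyte, myeloid, B cell and plasma cell markers. All 26 cell cycle genes were higher, with a median of 0.68 (camera adjusted p = 3.49e-08; adjusted p = 0.806 with an estimated correlation). The proliferation marker Mki67 was at 1.59 and Ube2c at 1.13, and none passed singly. Of 19 heat shock and unfolded protein response genes, 18 were higher, with a median of 1.15 (camera adjusted p = 2.35e-08; adjusted p = 0.585 with an estimated correlation). The chaperone gene Hsph1 was at 2.28 (adjusted p = 0.615) and Herpud1, which acts in degradation of endoplasmic reticulum proteins, at 2.15 (adjusted p = 0.829). Knockout replicate 2, where plasma cell and myeloid markers were highest (median differences of 1.93 and 1.08 from the other knockout arrays), had 14 of 19 heat shock genes higher, with a median difference of 0.62, and 25 of 26 cell cycle genes lower, with one of -0.38. Oxidative phosphorylation had a median of 0.57 (camera adjusted p = 0.000809; adjusted p = 0.866 with an estimated correlation), and glycolysis one of 0.56 (camera adjusted p = 0.0286; adjusted p = 0.866 with an estimated correlation). In the 5-array fit, these medians were 0.38 for cell cycle, 0.60 for heat shock, 0.08 for oxidative phosphorylation and 0.07 for glycolysis. Glycolysis was then not called (camera adjusted p = 0.145), nor was it with the filter on the lowest 60%, with array quality weights or after quantile normalization again (camera adjusted p = 0.133, 0.119 and 0.259), although Slc2a3, a glucose transporter gene, fell with a log2 difference of -0.82.

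**Figure D3:**
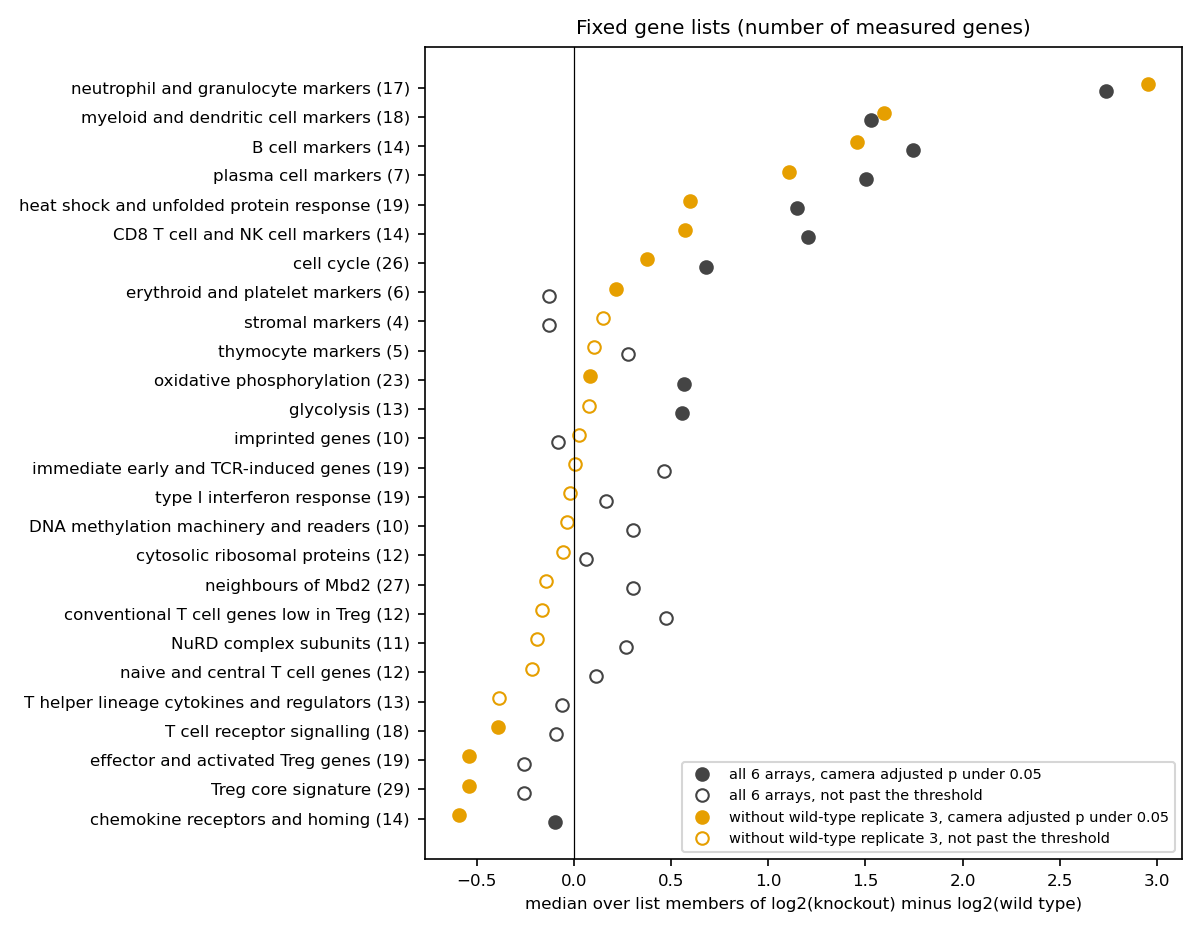
Median log2 difference, knockout minus wild type, over the measured genes of each of the 26 tested lists, with 6 arrays (dark) and without wild-type replicate 3 (orange); filled points had a camera adjusted p under 0.05. Granulocyte markers had the highest median in both fits (2.74 and 2.95), and the 4 lists that fell without wild-type replicate 3 had medians from -0.39 to -0.59.

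The remaining lists were not called in either of these 2 fits, although 2 of them were under other settings. Conventional T cell genes that are low in Treg had a median of 0.47 with 6 arrays (camera adjusted p = 0.478) and -0.16 without wild-type replicate 3 (camera adjusted p = 0.904), where median and test differed in sign. Igfbp4 was at 1.03 with 6 arrays. Immediate early and T cell receptor-induced genes had a median of 0.46 (camera adjusted p = 0.0767), with Fosb at 1.80 and Fos at 1.30. That list was called higher without the filter (camera adjusted p = 0.00356), with the mean of probe sets (camera adjusted p = 0.0317), without knockout replicate 1 (camera adjusted p = 0.0467) and without knockout replicate 3 (camera adjusted p = 0.0319). T helper lineage cytokines and regulators had a median of -0.06 and a mean of 0.02 (camera adjusted p = 0.206). They were called lower with the filter on the lowest 60% (camera adjusted p = 0.0276), with array quality weights (camera adjusted p = 0.00184), without knockout replicate 2 (camera adjusted p = 0.0274) and without both arrays (camera adjusted p = 0.00157). With 6 arrays and an estimated correlation both lists had an adjusted p = 0.866. With 5 arrays, Tnf and Rora of that list fell, at -0.86 and -0.82. Naive and central T cell genes (camera adjusted p = 0.851), type I interferon response genes (camera adjusted p = 0.718) and cytosolic ribosomal protein genes (camera adjusted p = 0.77) were not called. Their medians changed sign without wild-type replicate 3, from 0.11 to -0.22, from 0.16 to -0.02 and from 0.06 to -0.06, and those of the immediate early and T helper lists went to 0.01 and -0.39.

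Genes tied to DNA methylation were not called as groups. The list of DNA methylation machinery and readers had a median of 0.30 (camera adjusted p = 0.243), with Uhrf1 at 1.07 and the maintenance methyltransferase gene Dnmt1 at 0.99. Subunits of NuRD, the repressor complex that Mbd2 can join, had a median of 0.27 (camera adjusted p = 0.812), with Mbd3 at 0.19. Imprinted genes had a median of -0.08 (camera adjusted p = 0.326). Without wild-type replicate 3 these 3 medians changed sign, to -0.04 for methylation machinery, -0.19 for NuRD, with 10 of 11 genes lower instead of 2, and 0.03 for imprinted genes (camera adjusted p = 0.68, 0.235 and 0.347). Germline genes that DNA methylation silences in somatic cells were all below the filter. The 14 with a probe set had mean levels between 4.13 and 4.96, and 0 passed the threshold in a fit without the filter, with or without wild-type replicate 3. Of the 27 measured genes among 60 neighbours of Mbd2 on chromosome 18, 20 were higher and 7 lower, and the list was not called (camera adjusted p = 0.659). In the 5-array fit, the tally turned to 9 higher and 18 lower, with the median going from 0.31 to -0.14 (camera adjusted p = 0.445), and Ldlrad4 of that list fell, at -0.73.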

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

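All tests of explanations here were chosen after the results were seen, except the counts over other splits of the arrays.

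Among the control probe sets, which the comparisons leave out, the bacterial hybridization controls bioB, bioC and bioD were higher in every knockout array than in every wild-type array. The mean log2 differences were 0.947 for bioB, 0.786 for bioC and 0.525 for bioD, and that of cre, the most abundant of these controls, was 0.169 with overlapping groups. No processing batch was modelled. A difference in array processing that follows the groups could not be told apart from genotype, and its effect on the comparisons was not tested.

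The granulocyte and myeloid genes were higher in knockout arrays by at least 9.40-fold to 34.9-fold among the called genes with a symbol. The aberrant signal of wild-type replicate 3 is argued against as the source of the granulocyte rise. In the fit without that array all 17 granulocyte markers were higher and 12 passed the threshold. The 10 genes called with 6 arrays stayed past the threshold too. That adds little, since a call with 6 arrays favoured genes where this array lay near the other wild-type arrays. Granulocyte markers also differed between wild-type preparations: 15 of 17 were higher in replicate 2 than in replicate 1, with a median difference of 0.33. Of the 18 T cell receptor signalling genes 6 were higher there, with a median difference of -0.02. These wild-type differences were not tested. More cells of other types in the knockout preparations was tested in 2 versions, neither of which can decide. The first version took the knockout array with the highest granulocyte list median, replicate 1. There 11.1% of T cell receptor signalling genes and 5.56% of myeloid markers lay on the side that more foreign cells would give. By its rule this went against the explanation. But 12 of the 17 granulocyte markers were lower in replicate 1 than in the other knockout arrays. The version therefore did not test an array rich in these markers, and its outcome says nothing against the explanation. The second version was chosen after that outcome and after the lists of replicate 2 had been seen, so it is no independent test. It took the array where single granulocyte markers were highest, replicate 2. There 94.4% of T cell receptor signalling genes were lower and 100% of myeloid markers higher than in the other knockout arrays. In replicate 3, all 17 granulocyte and 17 of 18 myeloid markers were lower than in the other knockout arrays. There 17 of 18 T cell receptor signalling genes were higher. Member by member, the knockout arrays thus varied as a varying share of other cells would make them. These are single-array values within the knockout group and do not test the difference between the groups. Between the groups, without wild-type replicate 3, all 14 B cell, 7 plasma cell and 18 myeloid markers were higher in knockout. So were 13 of 14 CD8 T cell and NK cell markers. Of 18 T cell receptor signalling genes 17 were lower, against 12 with 6 arrays, and none passed the threshold. More cells of other types would give this pattern, although the stromal and thymocyte lists were not called. Expression by T cells lacking Mbd2 is not excluded by it and stays open. That 0 germline genes passed cannot decide, since these genes need not share a mechanism with granulocyte genes. The magnetic separation is meant to leave out myeloid cells, and its purity was not analysed here. The groups and any difference in purity cannot be told apart.

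The Treg signature was lower in knockout arrays once wild-type replicate 3 was left out, and with array quality weights, which nearly left that array out. With the array kept, the signature was also called lower under the filter on the lowest 60%, quantile normalization again, or without knockout replicate 1 or 3. It was not called without wild-type replicate 1 or 2 (list medians 0.05 and 0.13) or without knockout replicate 2 (-0.10, camera adjusted p = 0.0995). Knockout replicate 2 as the only source of the fall seen without wild-type replicate 3 is argued against, since without both arrays its median was -0.53 and it was still called at the preset correlation (camera adjusted p = 3.76e-05) and by fry (adjusted p = 0.0256), though not with an estimated correlation (adjusted p = 0.397), as with 5 arrays. Dilution by other cells predicts that Treg and T cell receptor genes fall alike; the difference of their list medians was -0.45 (exact two-sided permutation p = 0.2), and with list means, tried later, -0.09 (exact p = 0.5). A lower share of Treg among T cells predicts a rise of conventional T cell genes against T cell receptor genes; that difference was -0.093 by medians (exact two-sided permutation p = 0.4) and 0.36 by means (exact p = 0.1), so its sign depends on the summary. Over 5 arrays the smallest possible p is 0.1, so neither can be excluded, and an effect of Mbd2 on these genes in Treg remains as an untested hypothesis.

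Wild-type replicate 3 differed from the other 5 arrays. A swap with a knockout array is argued against, since no knockout array was out of place: the highest lay 2.53 and 2.02 below the lower of the other wild-type arrays on the brighter and the dimmer Mbd2 probe set. Wild-type replicate 3 itself lay 1.70 above the highest knockout array and 0.33 below that wild-type array on the dimmer one, picked after the data were seen for its smaller spread, but 0.80 above and 1.73 below on the brighter one, which places it between the groups. A change of scale that keeps the order of probe sets is argued against too, since its highest Spearman correlation with another array was 0.699, against a lowest value of 0.958 among the others. A wrong label of this array alone, another RNA source, a labelling failure or separate normalization remain open and were not tested.

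Splitting the 6 arrays 3 against 3 gives 10 splits, too few for a share under 0.05. The real split gave 14 probe sets and 10 genes, and the highest of the other splits gave 0 of each, so 1 of 10 splits gave as many. For gene lists the real split gave 10 and the highest other 13, and 3 of 10 splits gave as many.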

How the results depend on the processing

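Leaving out wild-type replicate 3 together with knockout replicate 2 was chosen after the data were seen, and the other settings before. The 14 probe sets and 10 genes became 8 and 5 with no filter, 2323 and 1417 with array quality weights (weight of wild-type replicate 3, 0.0289; the weight estimation stopped before converging), 2537 and 1645 without both arrays, and 524 and 350 at an unadjusted p under 0.05 with at least a 1.5-fold difference. Quantile normalization again gave 6 genes. Leaving out single arrays gave 0 to 190 probe sets, 0 to 129 genes and 9 to 13 lists: 190 probe sets without wild-type replicate 3, 0 without knockout replicate 1 or 2, and 3 without knockout replicate 3, though the log2 differences of the 10 genes kept their size there (3.19 to 5.24, against 3.49 to 5.12). The 10 genes were all among those called under array weights and without both arrays. The 10 called lists became 0 with an estimated correlation and 1 with fry, and ranged from 9 to 13 under the other settings. Mbd2 stayed lower under each setting, from -1.87 to -2.80 and from -1.91 to -2.18 with single arrays left out. Its probe sets passed the threshold with array weights (-2.69 and -2.31) and without both arrays (-2.70 and -2.21), and the dimmer one did after quantile normalization again (-2.04). Deviations from the group mean in same-numbered arrays had r of 0.15, -0.092 and -0.14. This cannot tell whether the replicate numbers pair the samples, since wild-type replicate 3 dominates the wild-type deviations. With the replicate block 10 probe sets, 7 genes and 9 lists passed, with glycolysis lost (camera adjusted p = 0.0581). The erythroid and platelet list turned from -0.13 to a called 0.22 without wild-type replicate 3, and ranged from -0.38 to 0.22 with single arrays left out. Cd1d1, not called at 0.28, was called at -0.37 with array weights and at -0.40 without both arrays. Of 440 list values under alternatives, 347 kept the direction of the test and the side of the threshold, though in 23 of these the list median changed sign, 27 lost and 29 gained the call, 1 reversed, and 36 changed the direction of the test without a call; of 309 values of named genes, 235 kept both, 44 lost and 30 gained the call. The cause of these changes was not tested. Low signal over background limits what can be said of the germline genes, all of which were below the filter.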

Other observations

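Sex-linked genes differed within the knockout group. Xist, the transcript of the inactive X chromosome, was at 10.32, 10.27 and 9.17 in wild-type replicates 1, 2 and 3 on its brightest probe set. It was at 10.32 in knockout replicate 1, but at 6.06 and 5.45 in knockout replicates 2 and 3. On the other Xist probe sets wild-type replicate 3 lay between the groups of arrays, at 6.44 and 5.75. There wild-type replicates 1 and 2 and knockout replicate 1 were between 8.23 and 8.88, and knockout replicates 2 and 3 between 4.34 and 4.51. The Y-linked gene Eif2s3y was at 7.62 and 7.88 in knockout replicates 2 and 3 and between 4.05 and 4.17 in the other 4 arrays. The labels used here give no sex, and no fit by sex was made. Only knockout arrays had high Eif2s3y, so any effect of sex is partly mixed with genotype in every comparison of the groups.

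Immune cell lists also differed between knockout arrays. In knockout replicate 2 all 7 plasma cell markers were above the mean of the other knockout arrays, with a median difference of 1.93, and 13 of 14 CD8 T cell and NK cell markers were, with a median difference of 1.14. In the same array 17 of 18 T cell receptor signalling genes were lower, with a median difference of -0.56. The lists also differed between wild-type replicates 1 and 2. All 14 B cell and all 7 plasma cell markers were higher in replicate 2, with median differences of 0.63 and 0.44. Of 18 myeloid markers 13 were higher there (0.15), and of 14 CD8 T cell and NK cell markers 10 were (0.20). These are single-array values with no test.

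The log2 difference between the 3' and 5' control probe sets was 0.23 for Gapdh and 0.64 for Actb in wild-type replicate 3, and between -0.01 and 0.17 for Gapdh and between 0.46 and 0.66 for Actb in the other 5 arrays.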
